A study of Mus musculus with 4 samples.

How the data were processed

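Droplet single-cell RNA sequencing (3' libraries, version 3 chemistry) was analysed from whole blood and ear skin of C57BL/6J mice aged 6 to 8 weeks. The mice had received 250 µg of rabbit IgG 3 times a week for 2 weeks. The IgG was either raised against the vWFA2 domain of collagen VII, which models the blistering disease epidermolysis bullosa acquisita (EBA), or control rabbit IgG (IgG). Cells of 3 mice were pooled before loading, which gave 4 libraries, 1 for each group: IgG blood, EBA blood, IgG skin and EBA skin. There are therefore no replicates. Blood was freed of red cells by lysis and skin was digested with enzymes, so digestion and tissue go together. The submitters' processing notes state that reads were aligned to mm10 with Cell Ranger 3.0.0 and that Seurat 3.0.0 and 3.1.0 were used afterwards. The deposited matrices hold UMI counts per gene and barcode (unit: counts) for 31053 features. All values were whole numbers, and no cell annotation was used, because none was among the files analysed here. Gene positions were taken from GENCODE mouse release 21 (GRCm38), which held 30934 of the gene identifiers.

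The libraries held 5008, 5113, 6770 and 6300 barcodes in the order given above, with 22705634, 37508438, 90829463 and 81861688 UMIs. Barcodes with fewer than 200 detected genes (356, 1489, 297 and 1135) and those with over 10% of their UMIs from mitochondrial genes (149, 253, 1390 and 1445) were removed. Doublets were scored with Scrublet in scanpy 1.11.5, and the barcodes with the highest scores were removed, as many as 0.8% for each 1000 barcodes (163, 94, 228 and 147). Scrublet's automatic threshold marked only 2 and 3 barcodes in the skin libraries and was used as an alternative alone. This left 4349, 3325, 5106 and 4134 barcodes, with median depths of 3741, 5763, 10613 and 9100 UMIs.

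Kept barcodes of all 4 libraries were clustered together in scanpy without batch integration. Counts were scaled to 10000 per barcode and log-transformed, and 2000 variable genes were chosen with library as the batch key. Every gene of the fixed lists below, mitochondrial genes and ribosomal protein genes were left out of that choice. The first 30 principal components, 15 neighbours and Leiden resolution 1 gave 35 clusters with random seed 0. Clusters were named "X-like" from 168 marker genes of 25 cell types fixed before the data were examined. A cluster that rested on fewer than 3 detected markers, or whose leading genes went against its name, stayed unnamed. Cluster 15 of the skin libraries, which mixed Langerhans cell, macrophage and dendritic cell markers, stayed unnamed for that reason, as did the small cluster 4 of blood. Shares of barcodes carry exact Clopper-Pearson 95% intervals.

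Within a library, raw UMI counts were summed over the barcodes of a class and expressed as CPM, the count scaled to the total of that sum. The ratio of 2 sums carries the exact conditional 95% interval (Clopper-Pearson on the split of the counts). Intervals and floors cover counting error only, not the difference between animals or between library preparations. With 1 pooled library in each group no test was possible, so no p-values are given, and values are described as higher or lower by size alone. A gene was measured in a comparison with 10 or more UMIs over both sums and 10 or more CPM in the higher one. It was called higher or lower when its ratio was 2 or more, or 0.5 or less, and its interval excluded 1. A gene with no UMI in one sum was set against a floor of 3 counts in that sum. Where the median log2 ratio of all measured genes differed from 0 by more than 0.1, ratios, calls and list medians were also taken relative to it.

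Before any data were examined, 24 gene lists with 332 genes were fixed, and 331 were matched (Clec7a was not analysed here). They covered C-type lectin receptors and their signalling, Fc receptors, other innate pattern receptors, inflammatory cytokines, chemokines, adhesion and migration, granule proteins, NADPH oxidase, interferon response, NF-kB targets, immediate early and heat shock genes, glycolysis and hypoxia, antigen presentation, complement, the tissue macrophage programme, cell cycle, the dermal-epidermal junction, epidermal wound and inflammation, the cornified envelope, fibroblast matrix, fibroblast inflammatory genes, endothelial activation and T cell effectors. The median log2 ratio of the measured members was given with its percentile among 10000 random lists of the same size matched on mean expression. Named genes were the 12 highest ranked in each direction in the neutrophil comparisons, and 6 in the others, by the bound of the ratio's interval nearest to 1 among genes with 100 or more CPM in the higher sum. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor and marker genes were left out of this ranking, as were gene models. So was any gene under 0.5 times its CPM in the other cells of the same library, a candidate for free RNA. Any C-type lectin receptor could be named, and up to 5 called members of every other list, those with the highest CPM. For shares of cells with a UMI, each cell was thinned to 500 UMIs. Comparisons needed 20 neutrophil-like barcodes, or 50 of another class, in both libraries.

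The procedure was tested on simulated data made from the same sums. Intervals covered the true ratio in 94.4% to 97.5% of genes. A 4-fold higher gene was called in 100% of cases in the skin and blood neutrophil comparison and in 83.9% in the endothelial comparison, the smallest, while a 2-fold higher gene was called in 51.0% and 33.5%, and the limit for passing this check was lowered after the value of 83.9% was seen. A gene with a true ratio of 1 was called higher or lower in at most 0.910% and 1.03% of cases. Each simulation placed 200 changed genes at random, so list members could be among them. Percentiles under 2.5 or over 97.5 came up in 4.04% to 8.33% of simulated lists, the most in the keratinocyte comparison, where 5% would be nominal. Genes were drawn independently of each other, so this rate does not cover lists whose members vary together. The alternatives tried were the Leiden resolution, the doublet, mitochondrial and gene number filters, naming cells by marker UMIs alone, 3 other scalings, other CPM minimums, subtraction of free RNA and thinning. Further ones were chosen after seeing the data: leaving out cluster 14, counting cluster 4 as neutrophil-like, leaving erythroid-like barcodes out of the denominator, leaving Clec1b out of its list, leaving out barcodes with a UMI of the platelet genes Pf4 or Ppbp, and single clusters of keratinocyte-like and fibroblast-like cells. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.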

Results

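Single-cell transcriptomes were collected from blood and ear skin of mice injected with IgG against collagen VII, the anchoring fibril protein of the skin (EBA), and of mice injected with control rabbit IgG. Each of the 4 groups was 1 library of cells pooled from 3 mice, so there were no replicates. Total depth was 22705634 UMIs in IgG blood, 37508438 in EBA blood, 90829463 in IgG skin and 81861688 in EBA skin. After filtering, 4349, 3325, 5106 and 4134 barcodes were kept in that order. The series asks how neutrophils that enter the diseased skin differ from those in the circulation, with C-type lectin receptors as the receptors of interest.

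Neutrophil-like cells, named from markers such as S100a8, S100a9 and Csf3r, made up 21.3% of kept barcodes in EBA skin (880 cells, 20.05% to 22.6%). A single neutrophil-like barcode was found in IgG skin, 0.0196%. The labels do not say how barcodes were filtered before the matrices were made, which limits what a near-absence of low-depth cells such as neutrophils can mean. In blood they made up 23.9% in EBA (795 cells, 22.5% to 25.4%) and 10.4% in IgG (452 cells, 9.502% to 11.3%). Among haematopoietic classes of EBA skin alone, with cluster 15 counted in and erythroid-like barcodes left out, their share was 47.1% (44.8% to 49.4%). Macrophage-like cells made up 8.22% of EBA skin and 2.43% of IgG skin, mast cell-like cells 0.992% and 0.235%, and the unnamed cluster 15, led by the Langerhans cell gene Cd207, 9.43% and 2.27%. Over haematopoietic classes alone these shares were lower in EBA than in IgG skin. Macrophage-like cells then held 18.2% and 30.3%, mast cell-like cells 2.19% and 2.93% with overlapping intervals, and cluster 15 20.9% and 28.4%. Basophil-like cells numbered 19 in EBA skin (0.460%) and 0 of 5106 in IgG skin, which allows a share of up to 0.0588% at 3 counts of the total. Keratinocyte-like cells made up 21.9% of EBA skin and 67.0% of IgG skin, fibroblast-like cells 19.9% and 14.2%, and hair follicle or sebaceous-like cells 1.16% and 3.78%. Chondrocyte-like (3.77% and 3.58%), vascular endothelial-like (1.28% and 0.979%), lymphatic endothelial-like (0.895% and 0.960%), mural-like (0.895% and 0.568%) and Schwann cell-like cells (0.702% and 0.783%) stood closer together. In blood, B cell-like cells made up 23.6% in EBA and 47.6% in IgG, T cell-like cells 18.8% and 27.7%, monocyte-like cells 10.05% and 5.93%, NK cell-like cells 5.50% and 5.33%, platelet-like barcodes 5.95% and 1.98%, and erythroid-like barcodes 7.64% and 0.483%. Erythroid-like barcodes also held 4.18% of EBA skin and 0.0196% of IgG skin. Shares of one class depend on all the others, and the neutrophil-like share of blood also varied with the filters: the difference of 13.5 percentage points was 21.5 with a mitochondrial limit of 5% and 20.97 with cells named by marker UMIs alone.

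**Figure D1:**
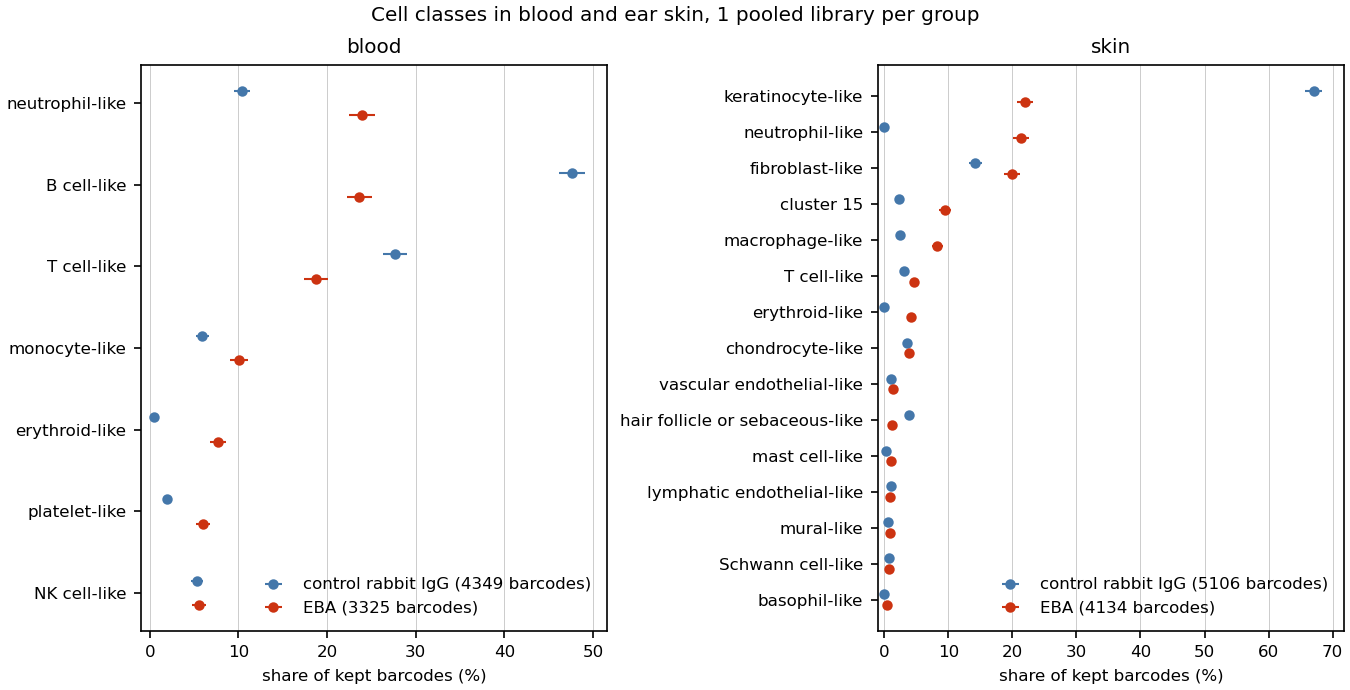
Share of kept barcodes (x axis, percent) in each cell class of the 4 libraries, with exact 95% intervals for counting error as bars. Neutrophil-like cells held 21.3% of EBA skin against 1 barcode in IgG skin, and 23.9% of EBA blood against 10.4% of IgG blood.

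The first comparison asks what sets neutrophil-like cells in EBA skin apart from those in EBA blood. Clec4d and Clec4e, myeloid C-type lectin receptors that signal through the Fc receptor gamma chain, stood at 2787 and 2962 CPM in skin and at 255 and 249.8 CPM in blood. Relative to all measured genes, which had a median log2 ratio of 0.27, these were 9.07-fold (8.67 to 9.49) and 9.85-fold (9.41 to 10.3) higher in skin. Clec4n, another activating receptor of this gene cluster, was 27.2-fold higher (17.9 to 43.1), and Olr1, a receptor for oxidised lipoprotein, 47.6-fold (31.3 to 75.7). Clec1a was 54.3-fold higher (14.2 to 462, from 2 UMIs in blood). The inhibitory receptors Clec4a2 and Clec12a were 3.43-fold and 8.04-fold lower in skin, Ly75 was 3.13-fold lower, and Clec1b, a platelet receptor, 614-fold lower (3 UMIs in skin). Clec5a (1.85-fold higher) and Clec2d (1.15-fold higher) passed the size limit in neither direction. Of the 21 receptors on the list, 11 were measured. Relative to all genes, 5 were higher, 4 lower and 2 neither, with a relative median of 0.89, and the CPM median of 1.16 lay at percentile 83.3 of matched random lists. The median thus lay within the range of matched lists. Without Clec1b the median was 2.30, for which no percentile was computed, so whether it would leave that range is not known. Clec4d and Clec4e lie beside each other on chromosome 6 (GRCm38, 123262111 to 123275265 and 123281789 to 123289870), with Clec4n at 123229843 to 123247021 and Olr1 at 129485244 to 129507165. Clec4a2 belongs to a family of near-identical genes, so its assignment is uncertain.

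In cells thinned to 500 UMIs, Clec4d was detected in 71.8% of neutrophil-like cells of EBA skin (68.7% to 74.8%), 13.5% of those of EBA blood (11.2% to 16.03%) and 36.7% of those of IgG blood. Clec4e was detected in 66.1% (62.9% to 69.3%), 12.1% (9.89% to 14.5%) and 10.4%. Keratinocyte-like cells of EBA skin, which should lack both receptors, gave a background of 0.221% for each. Without thinning the shares in EBA skin and EBA blood were 97.7% and 74.2% for Clec4d, and 94.2% and 83.3% for Clec4e, at median depths of 3026 and 9976 UMIs. The unthinned background was 7.95% and 5.96% at a median depth of 34547.5 UMIs. The cells came from different clusters. Cluster 34 held 879 of the 880 skin cells and was led by the inflammatory genes Acod1, Cd14, Ccl4, Ccl3, Ccrl2, Cxcl2 and Cxcl3, whereas cluster 10 (66.3%) and cluster 14 (32.8%) held those of EBA blood. Clec4d stood at 2791 CPM in cluster 34, 360.1 in cluster 10 and 75.6 in cluster 14 of the EBA libraries, and at 887 CPM in cluster 8, which held 90.5% of the neutrophil-like cells of IgG blood. Clec4e stood at 2966, 305 and 155 CPM in the EBA clusters and at 264 CPM in cluster 8.

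**Figure D2:**
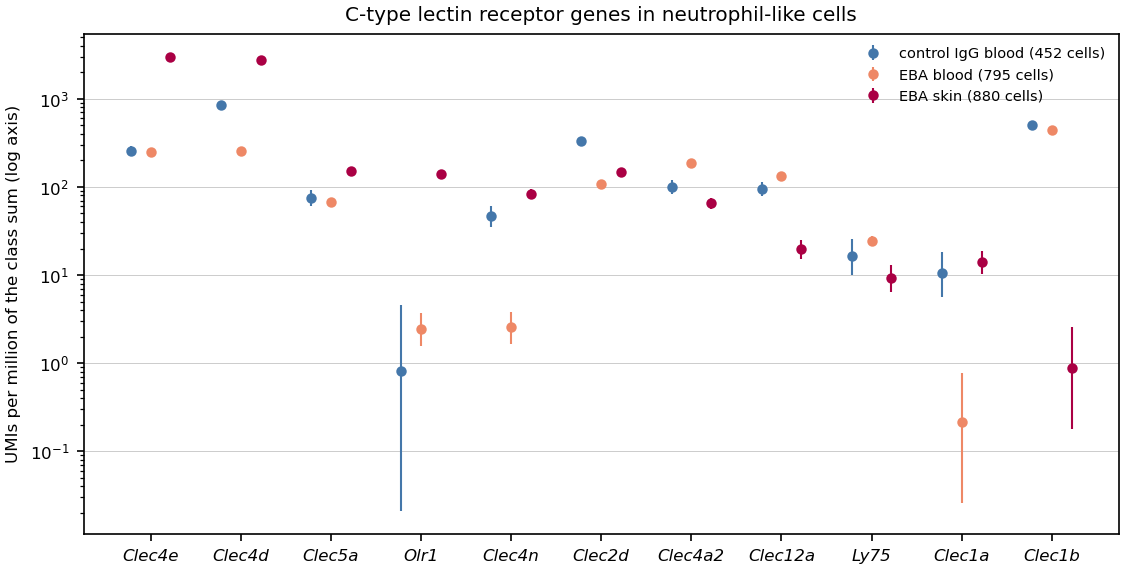
C-type lectin receptor levels (log-scale axis, CPM of the summed counts) in neutrophil-like cells of IgG blood, EBA blood and EBA skin, with exact 95% counting intervals as bars. Clec4d stood at 843, 255 and 2787 CPM and Clec4e at 259, 249.8 and 2962 CPM in that order.

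Inflammatory genes were the other large difference between the skin and blood cells. All 16 measured NF-kB targets were higher in skin (relative median 4.00, percentile 100), among them the inhibitor Nfkbia (2887 and 152 CPM, 15.7-fold relative to all genes), Ier3 (7.33-fold), Nfkbiz (10.9-fold), Plaur (3.30-fold) and the mitochondrial superoxide dismutase Sod2 (46.6-fold). Of 12 chemokines, 10 were higher and 1 lower (relative median 6.39, percentile 100). Cxcl2, which attracts neutrophils, held 31850.2 CPM in skin and 24.1 in blood, 1096-fold (962 to 1254), Ccl3 was 1644-fold and Ccl4 1003-fold higher, and Cxcl3 25393-fold from 1 UMI in blood (4557 to 1003070). Of 15 inflammatory cytokines, 13 were higher and none lower (relative median 3.53, percentile 100), with Il1b at 5629.85 and 512 CPM (9.13-fold), the interleukin-1 antagonist Il1rn 25.3-fold, Tnf 62.7-fold and Il1a at least 1202-fold higher. Other innate pattern receptors followed, with 11 of 15 higher and 2 lower (relative median 1.83, percentile 99.9), led by the lipopolysaccharide co-receptor Cd14 (33.5-fold), Nlrp3 (19.5-fold), Trem1 (5.74-fold) and Fpr1 (4.03-fold). Of 18 immediate early and heat shock genes, 12 were higher and 2 lower (relative median 1.93, percentile 99.99), such as Jun (13.9-fold) and Atf3 (63.9-fold). Among 9 measured genes of the tissue macrophage programme, 7 were higher and 1 lower (relative median 2.47, percentile 99.4). The matrix and cytokine-like gene Spp1 was 1323-fold, the haem-degrading enzyme Hmox1 39.7-fold and Thbs1 9.10-fold higher, and Chil3 was lower (relative ratio 0.0692). Glycolysis and hypoxia genes had 9 of 18 higher and none lower (relative median 1.02, percentile 95.9), including Hif1a (6.37-fold) and Ero1l (10.2-fold), and antigen presentation genes 5 of 9 higher and 2 lower (relative median 1.02, percentile 93.6). EBA blood, the reference here, itself stood below IgG blood for several of these lists. For immediate early and heat shock genes the CPM median was 2.20 for skin over EBA blood and −2.35 for EBA over IgG blood. For antigen presentation it was 1.29 and −2.06, and for NF-kB targets 4.27 and −1.76. Il1b was also lower in EBA than in IgG blood. EBA skin and IgG blood were not compared directly, so higher here is relative to EBA blood alone. The remaining genes named by rank were Ccrl2 (1404-fold), Saa3 (945-fold), the lipid droplet gene Hilpda (752-fold), the cell cycle inhibitor Cdkn1a (667-fold), the granulocyte growth factor Csf3 (at least 368-fold) and Nr4a3 (1560-fold, 279 to 61712, 1 UMI in blood).

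Granule protein genes stood on the other side, with 8 of 13 lower in skin and 4 higher (relative median −2.30, percentile 0.01). Camp, Ngp and Ltf encode proteins of the secondary granules made before neutrophils leave the marrow. Camp was 76.1-fold and Ngp 20.9-fold lower in skin, the lysozyme gene Lyz2 16.6-fold and Lcn2 4.92-fold lower, and Slpi was 3.73-fold higher. Interferon response genes had 7 of 12 lower and 1 higher (relative median −1.37, percentile 0.45): Ifitm3 was 2.84-fold lower and the checkpoint ligand Cd274 177-fold higher. NADPH oxidase genes had 3 of 6 lower and none higher (relative median −0.98, percentile 2.74), with Cybb 4.40-fold, Rac2 3.23-fold and Cyba 2.66-fold lower. Signalling genes downstream of the lectin receptors moved apart. Syk (2.34-fold) and Malt1 (14.7-fold) were higher and Card9 7.46-fold lower, and the list's CPM median of 0.25, like those of the Fc receptor, adhesion, complement and cell cycle lists, changed sign between scalings. Their relative medians were −0.02, 0.01, 0.04, 0.18 and 0.21 in that order. Dermal-epidermal junction genes had 1 of 4 higher and 2 lower (relative median −2.49). Lists of other cell types were also higher in the skin cells, with 13 of 14 wound keratinocyte genes (6.22), 8 of 9 cornified envelope genes (5.80), 3 of 4 fibroblast matrix genes (3.41), all 5 fibroblast inflammatory genes (6.52), 3 of 6 endothelial activation genes with 3 lower (2.28), and both measured T cell effector genes (4.50), as relative medians. Krt16 for example stood at 242 CPM in these cells and at 2815 CPM in the rest of the library. Of the 12 genes ranked lowest in skin, Nrgn (at least 899-fold), Gng11 (653-fold), Ctla2a (479-fold), Treml1 (at least 246-fold), Clec1b, Myl9, Alox12 and Bin1 (1 UMI each in skin for the last 3) are expressed by platelets. Serpinb1a (101-fold), Clu (93.5-fold) and Tsc22d1 (72.2-fold) completed them, with Camp. A UMI of the platelet genes Pf4 or Ppbp was present in 87.4% of these blood cells and in 2.73% of the skin cells.

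Some of these directions depended on the setting. Without the blood barcodes that held platelet UMIs, the interferon list median was 0.76, Selplg 0.04 and Oasl2 0.44 on the log2 scale, against lower values with them, and the dermal-epidermal junction median was 3.18 with a minimum of 1 CPM. The CPM median of the C-type lectin receptor list ranged from 0.41 with cells named by marker UMIs alone to 2.30 without Clec1b. T cell-like cells of control mice (155 in skin, 1203 in blood) also had all 16 measured NF-kB targets higher in skin than in blood (relative median 2.68). Of 18 immediate early and heat shock genes, 17 were higher (2.36). Inflammatory cytokines (5.39, 7 of 7 higher) and chemokines (6.32, 3 of 4 higher and 1 lower) were higher as well. Granule proteins (4.18) and antigen presentation genes (−1.22) went the other way than in the neutrophil-like cells. These T cell-like cells were of different kinds, as cluster 0 held 99.5% of those in blood and clusters 12 and 26 held 34.8% and 64.5% of those in skin.

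**Figure D3:**
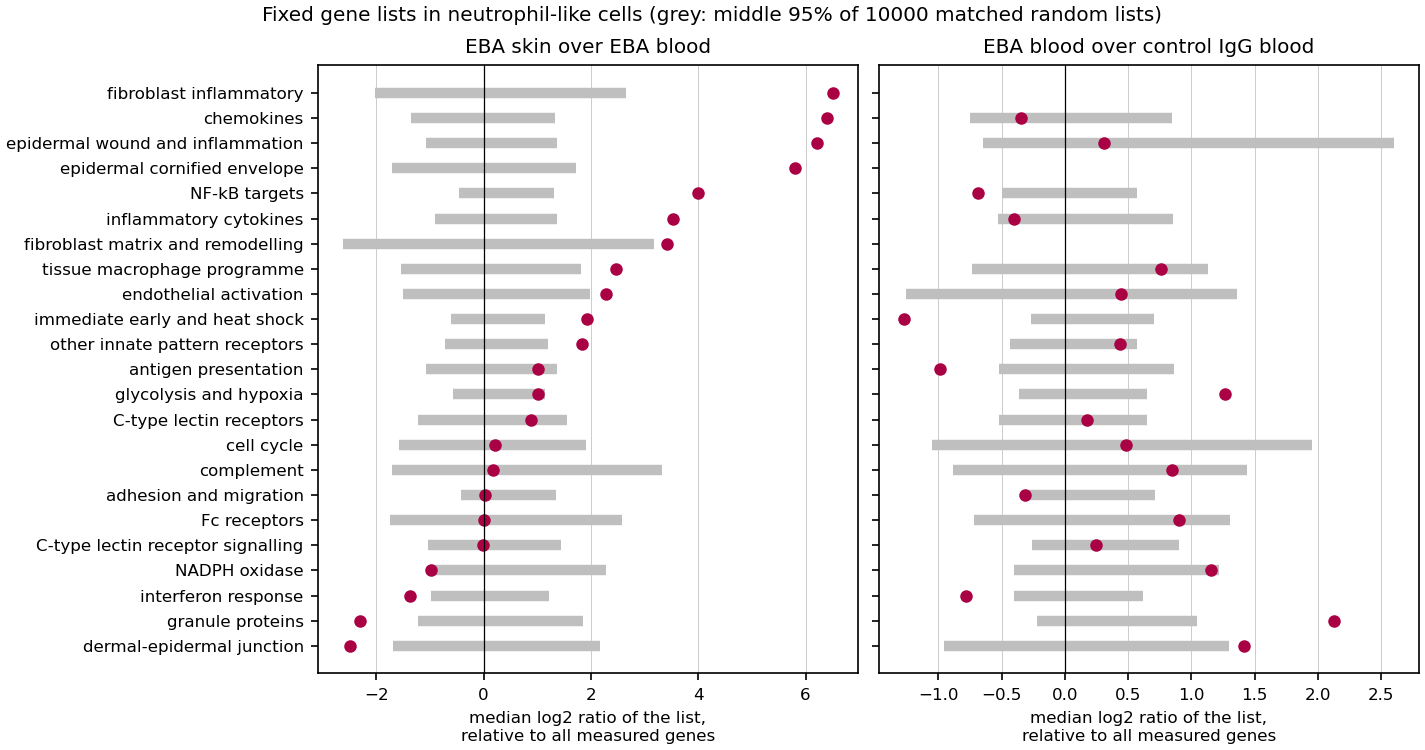
Median log2 ratio of each fixed gene list (points) in neutrophil-like cells, for EBA skin over EBA blood and for EBA blood over IgG blood. Grey bars hold the middle 95% of 10000 matched random lists. Points and bars are drawn relative to the median of all measured genes (0.27 and −1.07 in that order). In skin over blood, NF-kB targets (CPM median 4.27) and chemokines (6.66) lay above the bars and granule proteins (−2.03) below. Under other scalings the CPM medians of the lectin receptor signalling, Fc receptor, adhesion, complement and cell cycle lists in that panel flip sign. In the blood panel the receptor list and 8 others do so. Their CPM medians lay between −0.90 and −0.17, but relative to all genes they are drawn with positive values.

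The same tissue comparison in control mice, and EBA against IgG within skin, could not be made for neutrophils, because IgG skin held 1 neutrophil-like barcode and 20 were required.

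The next comparison asks how circulating neutrophil-like cells of diseased mice differ from those of control mice. In EBA blood the secondary granule genes were far higher: Ngp stood at 12999 CPM against 4.11, Camp at 7877 against 1.64 (2 UMIs) and Ltf at 3006 against 0.822 (1 UMI). The median log2 ratio of all 5986 measured genes was −1.07, and relative to it Ngp was 6656-fold higher (2852 to 20500.4), Camp 10084-fold (2791 to 83270) and Ltf 7697-fold (1381 to 304038). The other genes ranked highest were Chil3 (663-fold), Prok2 (at least 229.8-fold), Acvrl1 (145-fold, 40.1 to 1199, from 2 UMIs), Adpgk (119-fold), Ifitm6 (89.8-fold), Mgst2 (56.0-fold), Serpinb1a (53.9-fold), Cd177 (37.9-fold), an adhesion receptor of neutrophils, and Lcn2 (35.6-fold, 33.4 to 37.9). Of 13 granule protein genes, 8 were higher and none lower relative to all genes (relative median 2.13, percentile 99.98). Relative to all genes, 10 of 17 glycolysis and hypoxia genes were higher and none lower (1.26, percentile 100), with Gapdh 5.42-fold and Pgk1 4.46-fold, but by CPM 2 were higher, 2 lower and 13 neither (0.19). Of 6 NADPH oxidase genes 5 were higher in relative terms (1.16), with Cybb 20.7-fold, but 1 higher, 1 lower and 4 neither by CPM (0.08), and the list at percentile 96.8 lay within the middle 95% of random lists. Genes of recent activation were lower. Of 17 immediate early and heat shock genes, 9 were lower and none higher (relative median −1.27, percentile 0), such as Dusp1 (relative ratio 0.414) and Btg2 (0.363). Counts for this and the following lists are relative to all genes. By CPM the medians were lower still, at −2.35 here, −1.76 for NF-kB targets, −2.06 for antigen presentation and −1.86 for interferon response genes. Ptgs2, the inducible prostaglandin synthase, was 44.9-fold, Egr1 20.5-fold and Atf3 15.6-fold lower. Of 14 NF-kB targets, 5 were lower, 2 higher and 7 neither (−0.69, percentile 0.41), and of 9 antigen presentation genes 4 were lower and 5 neither (−0.99, percentile 0.05). H2-K1 of that list turned to a log2 ratio of 5.56 when free RNA was subtracted. That step counts all haemoglobin UMIs of the cells as free RNA and took 48.6% of the UMIs of the IgG cells, which may be too much. Of 15 interferon response genes, 6 were lower, 2 higher and 7 neither (−0.78, percentile 0.04), and Ifitm1 (6.00-fold) and Ifitm3 (6.08-fold) were higher. Il1b was lower (512 and 4112 CPM, relative ratio 0.262) in a cytokine list with 3 of 9 lower and none higher (−0.40, percentile 6.51). The macrophage growth factor Csf1 was 8.36-fold, the retention receptor Cxcr4 5.44-fold, Arl4c 8.998-fold, Fgl2 6.51-fold, Arrdc3 5.75-fold, Zeb2 5.56-fold, H2-Q10 5.26-fold, Gngt2 4.87-fold and Mpeg1 4.48-fold lower.

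Among C-type lectin receptors in blood, Clec4d stood at 255 CPM in EBA and 843 in IgG (relative ratio 0.638, 0.592 to 0.687), and Clec4e at 249.8 and 259 CPM, 2.03-fold higher relative to all genes. Clec4a2 (3.91-fold), Clec12a (2.92-fold) and Ly75 (3.103-fold) were also higher in relative terms, and Clec4n (0.115), Clec4a1 (0.0940), Clec4a3 (0.232) and Clec1a (0.0421) lower, as relative ratios. None of the receptors that were higher in relative terms passed the size limit by CPM. Over the 12 measured receptors the median was −0.90 by CPM and 0.18 relative to all genes, with the sign depending on the scaling, as it also did for Clec4e. These cells came from different clusters, cluster 8 in IgG and clusters 10 and 14 in EBA, and from different depths (median 2424 and 9976 UMIs). The receptor median ranged from −1.63 without Clec1b to 0.14 under median-of-ratios scaling, and without barcodes holding platelet UMIs Cd14 and Ifitm1 turned to −0.98 and −2.22 on the log2 scale.

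In the other cells of the skin, the question is what differed between diseased and control mice. Keratinocyte-like cells of EBA skin (906, against 3423 in IgG skin) had higher wound genes, with 11 of 17 higher and none lower (relative median 1.79, percentile 100, all-gene median −0.11). The keratins of activated epidermis Krt16 (4898 and 595 CPM, 8.90-fold), Krt6a (25.2-fold) and Krt6b (61.1-fold), the cornified envelope precursor Sprr1b (3.45-fold) and Sprr2d (7.86-fold) were among them. The protease inhibitors Stfa1 (33.02-fold), Stfa3 (32.6-fold) and Stfa2 (30.2-fold), with Sprr2a3 (26.2-fold), were the other genes ranked highest. Counts of Krt6a and Krt6b, of the Stfa genes and of Sprr2a3 may be shared between near-identical copies, so the split among them is uncertain. Cytokine genes (5 of 10 higher, 0 lower, 0.97, percentile 100) included Il33 (3.40-fold), Il1f9 (3.17-fold), Vegfa (3.09-fold), Il23a (4.10-fold) and Il1b (4.20-fold), and glycolysis genes had 10 of 17 higher (1.16, percentile 100). Il1b was abundant in neutrophil-like cells, and S100a8 and S100a9 took 0.328% of the UMIs of keratinocyte-like cells in EBA and 0.00697% in IgG, with 3 of 7 granule protein genes higher (0.85, percentile 99.6). In EBA skin, S100a8 and S100a9 took 0.0326% in fibroblast-like, 0.0391% in T cell-like, 0.0542% in macrophage-like and 0.425% in mast cell-like cells. Whether the keratinocyte-like cells made this RNA themselves or took it up from neutrophils was not tested. Genes of the junction that the antibody targets gave a relative median of −0.01 over 11 measured, with Lama3 (2.18-fold) higher and Dst lower (relative ratio 0.406). Ccnd2 (3.77-fold), Kif21a (3.75-fold), Igfbp3 (2.73-fold), Serpinb7 (2.69-fold), Lce1m (2.65-fold) and the filaggrin relative Flg2 (2.62-fold) were lower. The fixed cornified envelope list, which held neither Lce1m nor Flg2, had a CPM median of 0.14. Different clusters held the class: cluster 17, led by Krt6b and Stfa3, had 49.9% of the EBA and 2.19% of the IgG cells, while cluster 19, led by Krt15 and Krt5, had 12.8% and 38.5%. Within cluster 19 alone the wound list's CPM median was 0.89 against 1.68 for all clusters.

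**Figure D4:**
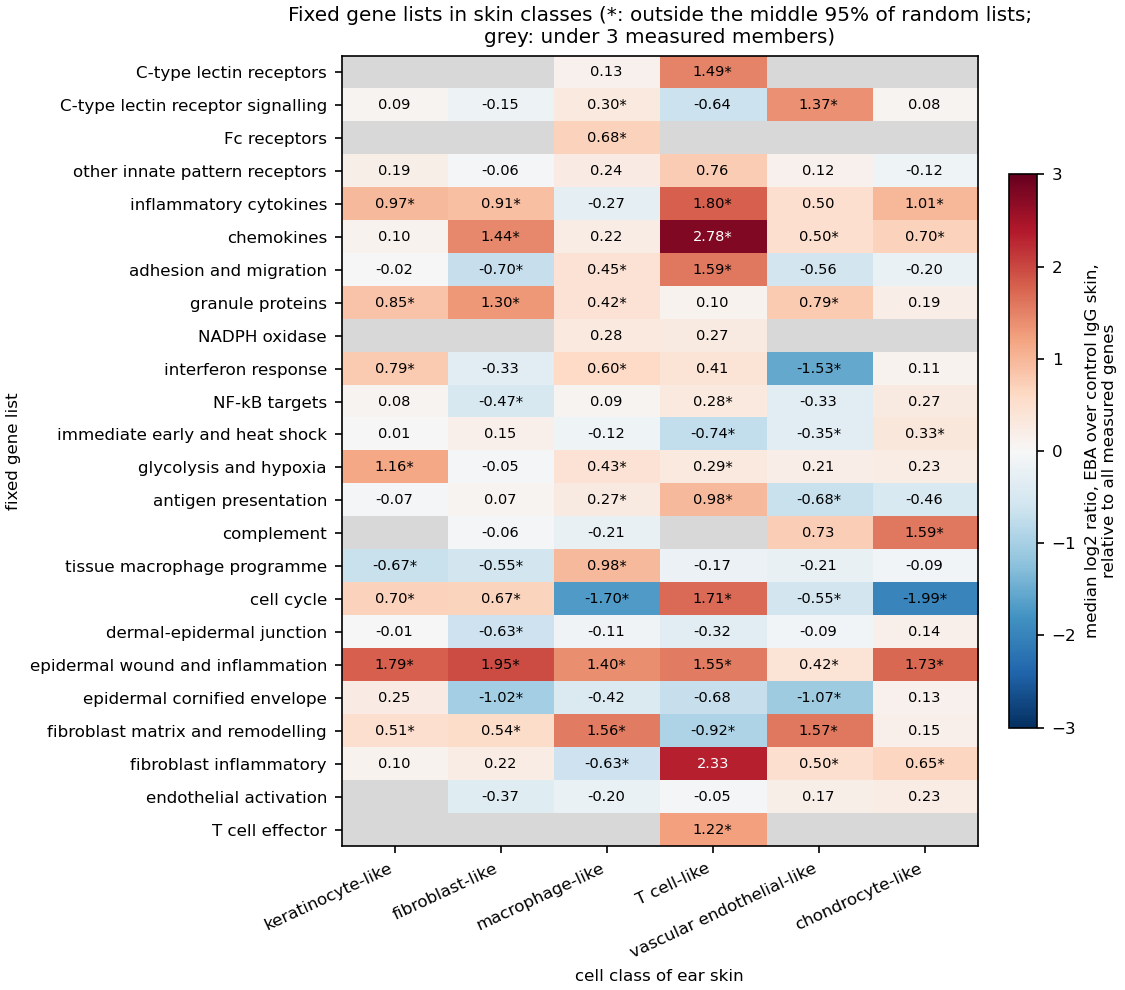
Median log2 ratio (colour scale), EBA skin over IgG skin, of each fixed list in the skin cell classes, relative to all measured genes of that class; asterisks mark medians outside the middle 95% of matched random lists and grey marks fewer than 3 measured genes. The wound list gave 1.79 in keratinocyte-like cells and the interferon list −1.53 in vascular endothelial-like cells; by CPM, small medians such as that of the chemokine list in keratinocyte-like cells changed sign between scalings.

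Fibroblast-like cells of EBA skin (821, against 726) had higher chemokines, with 8 of 13 higher and none lower (median 1.42, percentile 100). The neutrophil attractant Cxcl5 was 7.87-fold higher (7.23 to 8.57), Cxcl12 3.06-fold and Cxcl2 3.00-fold. Neutrophil RNA was also higher in these cells, with a granule protein median of 1.29 (percentile 100) and S100a8 and S100a9 at 0.0326% of UMIs in EBA and 0.000449% in IgG, and neutrophil-like cells of EBA skin held far more Cxcl2. The acute phase genes Hp (115-fold, 83.8 to 163) and Saa3 (8.70-fold), with Chl1 (14.5-fold), Fabp4 (5.93-fold) and Sfrp1 (4.94-fold), were ranked highest. Collagen VII itself, Col7a1, stood at 307 and 129.96 CPM, 2.36-fold higher. The matrix list had 4 of 15 higher and none lower (0.52, percentile 99.9), with Tnc 2.27-fold, Timp1 2.97-fold and Lox 2.17-fold, and the inflammatory list 5 of 15 higher and 1 lower (0.20, percentile 96.1). NF-kB targets gave −0.49 (percentile 0.16) with 1 of 13 lower. Myoc (12.5-fold), the Wnt inhibitor Wif1 (5.84-fold), Ltbp4 (4.84-fold), Igfbp6 (4.24-fold), Apoe (4.22-fold) and Gsn (3.53-fold) were lower. Cluster 16 held 78.4% of the IgG cells and cluster 24, led by Col3a1 and Col1a1, 81.9% of the EBA cells. Within cluster 24 alone the matrix median was 0.03 and the log2 ratio of Gsn 0.42. Cluster 16 alone was not rerun.

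Macrophage-like cells (340 in EBA, 124 in IgG skin) had 6 of 13 genes of the tissue macrophage programme higher and none lower (median 0.98, percentile 100). Fibroblast matrix genes had 4 of 7 higher (1.55, percentile 100), granule protein genes 3 of 7 (0.42, percentile 99.2), and S100a8 and S100a9 took 0.0542% of UMIs in EBA and 0.000935% in IgG, so RNA of other cells is not separated from these values. The arginine-degrading enzyme Arg1 was at least 31.1-fold, Chil3 37.0-fold (16.9 to 101), the adhesion molecule Vcam1 11.4-fold, Spp1 6.50-fold, Ccl6 5.07-fold and Ccr1 3.57-fold higher. The IgG receptors Fcgr1 (2.33-fold) and Fcgr4 (5.51-fold) were higher in a list with a median of 0.68 (percentile 99.8). Cell cycle genes had 8 of 13 lower (−1.71, percentile 0), including Mki67 (ratio 0.222) and Top2a (0.339). Cd209g (10.2-fold), Mgl2 (5.17-fold), Cd209d (4.99-fold), Hpgd (4.55-fold), the transferrin receptor Tfrc (4.11-fold) and the monocyte attractant Ccl2 (3.59-fold) were lower. Over 14 measured C-type lectin receptors the median was 0.13 (percentile 78.3). None was higher, and Mgl2, Clec10a (ratio 0.329) and Colec12 (0.368) were lower, while Clec4d (392 and 269 CPM) and Clec4e (447 and 310 CPM) passed the limit in neither direction. Wound keratinocyte genes were higher in these cells too (median 1.39), with Krt16 at 114 and 24.5 CPM, and the list also had medians of 1.93 in fibroblast-like, 1.74 in T cell-like, 1.64 in chondrocyte-like and 2.19 in cluster 15 cells.

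T cell-like cells of the skin (191 in EBA, 155 in IgG) had higher effector genes, with 8 of 16 higher and 3 lower (relative median 1.22, percentile 100, all-gene median 0.19). The cytokines Il17f (24.4-fold, 12.3 to 56.8), Il17a (12.3-fold, 6.78 to 24.9), Il22 (12.3-fold, 3.24 to 104, from 2 UMIs) and Il5 (11.8-fold) and the activation receptors Tnfrsf4 (4.40-fold), Il2ra (2.48-fold) and Icos (2.19-fold) were higher, and Areg, a repair factor, lower (relative ratio 0.404). Cell cycle genes had 8 of 12 higher and 1 lower (1.71, percentile 100), including Mki67 (3.797-fold) and Top2a (2.80-fold). S100a8 and S100a9 took 0.0391% of the UMIs of these cells in EBA and 0.00160% in IgG, so RNA of neutrophils, in which Cxcl3 was abundant, is not separated from the chemokine values. The 4 measured C-type lectin receptors had a relative median of 1.49 (percentile 99.5) with 2 higher. Ccl5 was 28.4-fold, Zeb2 12.4-fold and Cxcl3 at least 29.8-fold higher, and Thbs1 (36.9-fold), Gzmc (10.1-fold), Nap1l5 (6.93-fold), Ier5l (5.77-fold), Cdk11b (5.42-fold) and Mest (5.24-fold) were lower. Cluster 12, led by Icos, Il2ra and Il17f, held 75.9% of the EBA cells, and cluster 26, led by the gamma-delta chain gene Trdc, 64.5% of the IgG cells. The cytokine list's median of 1.99 turned to −0.40 with a minimum of 50 CPM.

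Vascular endothelial-like cells were few (53 in EBA, 50 in IgG skin). Interferon response genes were lower in EBA, with 9 of 15 lower and none higher (median −1.50, percentile 0): Ifit1 was 17.7-fold, Isg15 4.08-fold and Gbp2 3.33-fold lower. Matrix genes had 7 of 12 higher (1.61, percentile 100), with Col6a3 5.26-fold and the basement membrane collagen Col4a1 3.59-fold higher. The fibroblast collagens Col1a1, Col1a2 and Col3a1 took 0.140% of the UMIs of these cells in EBA and 0.0308% in IgG, and haemoglobin 1.53% and 0.00816%, so RNA of other cells is not separated from this difference. The vascular growth factor Pgf (12.7-fold, 4.81 to 47.6), Slc7a11 (5.25-fold), Lgals1 (4.90-fold) and AA467197 (37.6-fold, 6.54 to 1507, from 1 UMI) were among those ranked highest, and Pcdh19 (3.62-fold), Pdzd2 (3.11-fold) and Cst3 (2.46-fold) were lower. Endothelial activation genes gave a median of 0.20 (percentile 95.7) with 2 of 13 higher and 1 lower. Chondrocyte-like cells of the ear cartilage (156 and 183) had higher complement genes, 4 of 7 with 1 lower (median 1.50, percentile 100), including C3 (4.04-fold) and C4b (3.83-fold), and lower cell cycle genes (4 of 7, −2.08, percentile 0). Lcn2 (16.3-fold), Serpina3n (6.6002-fold), Spp1 (6.30-fold), Pi15 (6.15-fold), the stromelysin Mmp3 (5.78-fold) and Prg4 (4.58-fold) were higher in them, with S100a8 and S100a9 at 0.0383% of UMIs in EBA and 0.000197% in IgG beside the granule gene Lcn2, and Lyz2 (16.5-fold), Htra1 (8.71-fold), Cilp (6.85-fold), Igfbp6 (5.49-fold), Mfap5 (5.34-fold) and Wfdc2 (4.53-fold) lower.

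The last comparison takes the other blood cells of diseased and control mice. Monocyte-like cells of EBA blood (334, against 258) had higher granule protein genes, with 13 of 15 higher and none lower (relative median 3.55, percentile 100, all-gene median −0.49). Ngp (at least 3176-fold), Ltf (at least 825-fold), Saa3 (at least 531-fold), Lcn2 (183-fold), Prok2 (at least 164-fold) and Wfdc21 (160.25-fold) were ranked highest. These genes were unevenly spread over the cells: 12.3% of them (41 of 334) held over 1% of their UMIs from Ngp, Ltf and Camp, and the median cell held 0.0107%. Cell cycle genes had 8 of 10 higher (3.54, percentile 100), such as Stmn1 (60.0-fold), Ube2c (24.4-fold) and Mki67 (at least 27.8-fold). Antigen presentation genes had 7 of 12 lower (−1.49, percentile 0), with the invariant chain Cd74 at 205 and 2130.15 CPM. Of 17 interferon response genes 7 were lower, 1 higher and 9 neither (−0.89), and of 16 NF-kB targets 7 were lower, 1 higher and 8 neither (−0.75). Clec4d (4.57-fold), Clec4e (6.73-fold) and Clec5a (5.88-fold) were higher, while Clec4a1 (0.465), Clec4b1 (0.387) and Clec10a (0.416) had lower relative ratios, and the 13 measured receptors gave a relative median of −0.29. The fatty acid carrier Cd36 (11.8-fold), Hpgd (8.20-fold), Bcl2a1b (6.01-fold), Grk3 (5.10-fold), Adgre4 (4.90-fold) and Cd300e (4.66-fold) were lower. Cluster 6, led by Chil3, Lyz2 and Ccr2, held 89.2% of the EBA and 57.8% of the IgG cells, and cluster 7, led by Ear2 and Cd300e, 10.8% and 42.2%. The neutrophil genes S100a8 and S100a9 took 15.1% of the UMIs of these EBA cells and 0.470% of those of IgG cells.

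Lymphoid cells of the blood were compared in the same way. In T cell-like cells (624 in EBA, 1203 in IgG; all-gene median −0.29) the cytokine feedback inhibitor Socs3 was 7.53-fold, Ly6a 5.66-fold, Ccl5 5.38-fold, Nkg7 2.38-fold, Cd7 2.20-fold and Hopx 2.07-fold higher. Interferon response genes had 5 of 13 higher and none lower (relative median 0.68, percentile 100), with Ifit3 2.62-fold. In B cell-like cells (786 and 2071; −0.33) Apoe (2.74-fold), Ly6a (2.21-fold), Tnfaip8l2 (2.13-fold), Slc25a4 (2.01-fold), Pold4 (1.92-fold) and Eef1b2 (1.80-fold) were ranked highest and Cxcr4 (2.53-fold), Chst3 (2.19-fold) and Hvcn1 (2.02-fold) were lower, and cluster 2 held 7.89% of the EBA and 28.01% of the IgG cells. In NK cell-like cells (183 and 232; −0.19) Tmem37 was 3.20-fold and Acp5 3.18-fold higher, Ccl4 2.41-fold lower, antigen presentation genes had 4 of 10 higher (0.62, percentile 99.6), and cell cycle genes had 4 of 10 lower (−0.87, percentile 0.06). Lars2 was lower in all 3 classes, 2.48-fold in T, 2.30-fold in B and 2.48-fold in NK cell-like cells. Of the granule protein genes, 3 of 5 were higher in T, 4 of 6 in B and 2 of 4 in NK cell-like cells and none lower, with relative medians of 1.55, 2.87 and 0.74, such as Lcn2 at 12.1 CPM in T cell-like cells of EBA blood and 0.143 (1 UMI) in IgG blood. The neutrophil genes S100a8 and S100a9 took 0.0247% of the UMIs in T, 0.0344% in B and 0.0349% in NK cell-like cells of EBA blood, and 0.00503%, 0.00162% and 0.00118% in IgG blood.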

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

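All barcodes of each library, kept or removed, were counted by what filled them, and 2 kinds were singled out because they were far more frequent in the EBA libraries. Barcodes with over 50% of their UMIs from haemoglobin genes made up 32.9% of EBA blood (1684 of 5113), against 7.29% of IgG blood (365 of 5008). In EBA skin they made up 12.2% (767 of 6300), against 0.694% of IgG skin (47 of 6770). Of these barcodes, 1426 in EBA blood and 582 in EBA skin had too few detected genes to be kept.

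Barcodes with over 50% of their UMIs from mitochondrial genes made up 0.802% of EBA blood (41 barcodes) and 0.140% of IgG blood (7 barcodes). In skin they made up 11.3% in EBA (709 barcodes) and 4.87% in IgG (330 barcodes).

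The share of T cell-like barcodes was singled out because its difference had opposite signs in the 2 tissues. Over all kept barcodes, EBA minus IgG was −8.89 percentage points in blood and 1.58 percentage points in skin. Whether these 2 differences differ was not tested. Over haematopoietic classes alone, EBA minus IgG was −5.62 points in blood and −27.7 points in skin. The opposite signs thus held with the first denominator only.

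Of the tests of the 3 patterns below, that of cluster 14 and that of free RNA for Clec4d and Clec4e, and that of azurophil granule genes for monocyte-like cells, were chosen after the result was seen. The comparison of clusters 8 and 10 for Clec4d and Clec4e had no rule set beforehand. The same holds for the values against cluster 10 alone and cluster 14 alone for monocyte-like cells. The other tests were written before their values were computed.

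Clec4d and Clec4e stood higher in neutrophil-like cells of EBA skin than in those of EBA blood. Cells of cluster 14 as the cause are argued against, because without them the lower of the 2 ratios was 7.74. Young cells in the rest of the blood class (cluster 10, Ngp at 5318 CPM) stay open for Clec4d, since cluster 8 of IgG blood, with Ngp at 4.67 CPM, held it at 887 CPM, but are argued against for Clec4e, which stood at 264 CPM in cluster 8, 305 in cluster 10 and 2966 in the skin cells. Free RNA from other skin cells is argued against as well, since the CPM of Clec4e in keratinocyte-like cells was 0.00145 of that in the neutrophil-like cells. Enzymatic digestion cannot be told apart from tissue entry: NF-kB targets in T cell-like cells of control mice had a median log2 ratio of 2.80 between skin and blood, below the 4.27 of the neutrophil-like cells but far above 0, in T cell-like cells that came from different clusters in the 2 tissues, and a response of neutrophils to the diseased skin stays open as untested.

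Camp, Ngp and Ltf stood higher in neutrophil-like cells of EBA blood than in those of IgG blood. Free RNA is argued against, because Ngp in T cell-like cells reached 0.000629 of the gap between the neutrophil-like sums. With each cell thinned to 500 UMIs the ratio of Ngp was 2330 (1 UMI in IgG blood). Thinning leaves each cell's expected share of a gene unchanged, so this ratio cannot decide on depth, which stays untested. Cells of cluster 14 held 74.3% of the Ngp UMIs of the class, but without them the lowest of the 3 ratios was still 1289. Release of young neutrophils in disease, and differences between the 2 blood preparations, stay open as untested.

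Granule protein and cell cycle genes stood higher in monocyte-like cells of EBA blood than in those of IgG blood. For azurophil granule genes, droplets shared with cells of the neutrophil-like class are argued against, because the median ratio of Mpo, Elane, Prtn3 and Ctsg in monocyte-like over neutrophil-like cells was 45.5. That median rests on few UMIs: Mpo, Elane and Ctsg stood at 0.107, 0 and 0.320 CPM in neutrophil-like and at 6.30, 29.9 and 10.2 CPM in monocyte-like cells. Cluster 4, led by Prtn3, was not in the reference, so droplets shared with its cells stay open. Free RNA is argued against, since T cell-like cells held 0.00262 of the Ngp CPM of the monocyte-like cells. For Ngp, Ltf, Camp and Lcn2, shared droplets cannot be told apart from expression by the monocyte-like cells: their median ratio to Retnlg, over that in neutrophil-like cells, was 0.493, just outside the limit of 0.5 set beforehand, with single genes from 0.395 to 0.694 on both sides of it. By the rule set beforehand this median counted against shared droplets. The spread of the single genes, which was not part of that rule, leaves the question open. Against cluster 10 alone the value was 1.48 and against cluster 14 alone 0.152, so it rests on which neutrophils serve as reference, and release of immature myeloid cells in disease stays open as untested.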

How the results depend on the processing

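No paired analysis was possible because each group was 1 library of pooled cells. Which results count as main answers was decided after the main values were seen, and so was the rule that a list median needs a size of at least 1 to be called. The cause of the differences below was not tested. Neutrophil-like cells of IgG blood were shallow (median 2424 UMIs), and subtraction of free RNA took 48.6% of their UMIs, so the blood comparison is the least settled. The subtraction counts all haemoglobin UMIs of a blood class as free RNA. Haemoglobin took 0.378% of the UMIs of these cells and 0.0291% of those of B cell-like cells of IgG blood, so 48.6% may overstate the free RNA. Leaving out barcodes with a platelet UMI left 100 and 73 blood cells.

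For the neutrophil-like share, EBA minus IgG in percentage points, skin gave 21.3, and 26.4 with a mitochondrial limit of 5%. Blood gave 13.5, and 21.5 with that limit, 15.6 at Leiden resolution 0.5, 15.4 without doublet removal and also with erythroid-like barcodes left out, 16.2 with Scrublet's automatic threshold, 17.2 with 500 genes, 20.97 with naming by marker UMIs alone and 17.1 with cluster 4 included.

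The C-type lectin receptor median of skin over blood neutrophil-like cells, 1.16, was 0.82 with Scrublet's threshold, 0.41 by markers alone, 0.51 under median-of-ratios scaling, 0.67 by CPM without the top genes, 0.90 thinned, 1.46 without cluster 14, 1.77 without platelet-UMI barcodes and 2.30 without Clec1b. Reversed log2 values were Fn1 at −0.44 (Scrublet's threshold) and −1.85 (markers alone), Apoe at −0.88 (markers alone), the dermal-epidermal junction median at 3.18 (minimum of 1 CPM), and, without platelet-UMI barcodes, the interferon median at 0.76, Selplg at 0.041 and Oasl2 at 0.44.

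The receptor median of EBA over IgG blood, −0.90, was −0.083 without doublet removal, −0.37 by markers alone, 0.14 under median-of-ratios scaling, −0.18 by CPM without the top genes, −0.17 with a minimum of 1 or of 50 CPM, −0.63 with free RNA subtracted, −0.10 thinned, −0.27 without platelet-UMI barcodes and −1.63 without Clec1b. Reversed values were Ccl5 at 0.13 (500 genes) and 0.43 (markers alone), H2-K1 at 5.56 and Apoe at 2.97 (free RNA subtracted), and Cd14 at −0.98, Ifitm1 at −2.22 and Tgm1 at −0.98 (platelet-UMI barcodes out).

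The keratinocyte wound median, 1.68, was 1.63 with the 5% limit, 1.76 with 500 genes, 1.77 under median-of-ratios scaling, 1.87 by CPM without the top genes, 2.25 by cell fractions, 2.05 with 1 CPM and 0.89 in cluster 19 alone. The fibroblast matrix median, 0.52, was 0.58 without doublet removal, 0.59 with Scrublet's threshold and under median-of-ratios scaling, 0.44 with the 5% limit, 0.595 with 500 genes, 0.76 by cell fractions and 0.032 in cluster 24 alone, where Gsn was 0.42. The macrophage receptor median, 0.13, stayed within its counting interval in every setting run, though it was −0.011 with the 5% limit. Leiden resolution 0.5 gave no value because too few cells were left. Naming by marker UMIs alone, free RNA subtraction and thinning were not run for this class. The cytokine median of skin T cell-like cells was −0.40 with 50 CPM, and the cornified envelope median of vascular endothelial-like cells 0.034 without doublet removal and with Scrublet's threshold.

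Over all results, 3743 of 5062 gene values stayed within the main counting interval, 1306 moved outside it and 13 reversed. A gene counted as reversed when its sign changed and it had been called higher or lower. Of 2990 list values, 2209 stayed within the interval, 776 moved and 5 reversed. A list counted as reversed only where its main median had a size of at least 1. Sign changes of smaller medians are therefore not among the 5. Of 20 shares, 11 stayed within the interval and 9 moved.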

Other observations

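None of the values below come from tests set before the data were seen. Cluster 15 of the skin, left unnamed, held 390 EBA and 116 IgG barcodes and was led by Cd207, the langerin gene of Langerhans cells, and Mmp12. Cd207 stood at 1861 CPM in EBA and 6656 CPM in IgG, 3.58-fold lower, and H2-M2 was 3.19-fold lower. Chil3 was 181-fold higher (77.4 to 557), Arg1 at least 53.5-fold, Ccl24 at least 64.9-fold, Spp1 25.5-fold and Mmp13 56.3-fold higher. Clec4d was 3.49-fold (2.99 to 4.08), Clec4e 2.20-fold, Clec4n 2.22-fold and Clec5a 5.30-fold higher in EBA, while Mgl2 (ratio 0.270) and Clec4b1 (0.473) were lower. Of the 15 measured receptors 6 were higher, 2 lower and 7 neither. S100a8 and S100a9 took 0.125% of the UMIs of cluster 15 in EBA and 0.000211% in IgG, and 5 of 8 granule protein genes were higher. RNA of neutrophils is thus not separated from these values. Of 13 genes of the tissue macrophage programme, 10 were higher and none lower.

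Keratinocyte-like cells of every cluster had higher Krt6b in EBA skin. Its ratio was 4.22 in cluster 17, 10.5 in cluster 18, 27.9 in cluster 19, 28.8 in cluster 20, 19.2 in cluster 21, 62.5 in cluster 22 and 251 in cluster 23 (69.2 to 2081). In clusters 18 to 21 of EBA skin Krt6b stood at only 22.4 to 37.1 CPM, against 2984 CPM in cluster 17. Free RNA from cluster 17 is not separated from those ratios. The wound list medians ran from 0.63 in cluster 21 to 2.24 in cluster 23. Krt16 passed the size limit in clusters 17 (ratio 2.24), 22 (6.96) and 23 (19.1), and in neither direction in clusters 18 (1.79), 19 (1.35), 20 (1.57) and 21 (0.544).

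The keratins Krt5, Krt14, Krt1 and Krt10 took 0.114% of the UMIs of neutrophil-like and of erythroid-like barcodes of EBA skin, 0.123% of those of chondrocyte-like and 0.0995% of those of T cell-like cells. Some monocyte-like cells of EBA blood might be young cells, as Mki67 stood at 27.2 CPM in them and 1.92 in neutrophil-like cells. The azurophil gene ratio, which rests on few UMIs in neutrophil-like cells, was 45.5. A sort of the monocyte-like cells by surface markers before sequencing, with several mice kept apart, could test whether some are young.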
